A study of Caenorhabditis elegans with 2 samples.

How the data were processed

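ChIP-seq against ELT-3 was done in whole L1 larvae in 2 biological replicates, per the labels, with chromatin sheared by sonication. Each replicate was called separately, both replicates were pooled for another list, and an IDR-thresholded set combined them. Each kind of list was deposited on ce11 and on ce10. Per the deposited records, the pooled and replicate lists were made from alignments of the ChIP and of a control, and the IDR set was derived from those lists. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here.

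The peak lists follow the narrowPeak layout without a header. The authors deposited a signal value per peak, which is never negative and whose scale differs between lists, so it was used to rank or filter peaks within a list. The authors also deposited a q-value score per peak, which is slightly negative for many pooled peaks and entered no test. Peak widths were nearly constant within a list. The median width was 284 bp in the pooled lists and the ce10 IDR set, 290 bp in replicate 1 on ce11, and 256 bp in the ce11 IDR set. All peaks lay on chromosomes I to V and X. Read depth is unknown, since no list gives read counts, and intervals on shares cover counting error over peaks or genes only.

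The main peak set was the IDR set on ce11, fixed before the data were examined together with the tests, gene lists and alternatives. Sequence and genes came from the WBcel235 assembly, which is ce11, and Ensembl release 115, with 19973 nuclear protein-coding genes. The ce10 lists were used for counts, overlaps and the X share only, the last against ce11 chromosome lengths. Coordinates are 1-based.

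Agreement between replicates was the share of the 1014 highest-signal peaks of replicate 1 overlapped by at least 1 bp by those of replicate 2, with 1000 circular shifts within chromosomes (one-sided permutation test). Location was tested by 1000 circular shifts of all summits (two-sided). Exon, intron and intergenic sequence were defined by protein-coding genes. The count on X was tested with an exact binomial test. WGATAR was searched on both strands within 50 bp of the summit and in a window 500 bp away on a random side, and compared with an exact McNemar test. Hexamers in the same windows were compared with Fisher's exact test per hexamer, which does not use the pairing of summit and flank. A gene was called bound if an IDR summit lay from 1500 bp upstream to 500 bp downstream of its 5′ end, so 1 peak could count for more than 1 gene, and 120 peaks did. The 22 lists were tested with Fisher's exact test against all other protein-coding genes, with conditional odds ratios. Peak strength was tested for lists with at least 10 bound genes by 100000 resamples. All tests over lists or hexamers carry Benjamini-Hochberg adjustment. Genes that share 1 symbol were counted separately, and binding at near-identical copies, such as histone genes, is uncertain. The symbols rol-9, hsp-16.11 and opt-2 matched no gene.

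The genes and sites named were those nearest to the 20 highest-signal IDR peaks, up to 4 bound members of each list with the highest signal, elt-3 and unc-119 in any case, and the 10 hexamers with the lowest adjusted p. The bound genes hpd-1 and tatn-1, the genes mdl-1 and nhr-3, the hexamer GACGCA, the gene classes, the alg-1 peak and the other peaks around elt-3 fell outside this rule and were chosen after their values were seen.

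The alternatives were the ce10 set, the 507 IDR peaks with the highest signal, IDR peaks overlapped in both replicates, the highest-signal peaks of 1 replicate alone, other overlaps and list lengths, other promoter windows (500 and 250 bp, 3000 and 1000 bp, or any transcript start), nearest gene only, other motif windows (25 and 100 bp), other motifs and control sequences, genes with a lettered symbol as background, a logistic model with upstream intergenic length, and leaving out genes within 50 kb of elt-3 or 20 kb of unc-119. The 1014 highest-signal pooled peaks were added after seeing the data, as were the single-replicate peaks for hexamers and, for results other than the peak count, the IDR peaks overlapped in both replicates.

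Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, with fixed seeds. The tests were tested on simulated data. For the list test over 19973 genes, a list bound at a raised rate and a list bound at a lowered rate were each called in 20 of 20 simulations, and unchanged lists in 2 of 400 tests. The planted lists were tyrosine and tryptophan catabolism and chemoreceptors, at rates close to those observed in the data. Genes were drawn independently, so the simulations do not measure false calls that arise when 1 peak counts for neighbouring genes. For the 2080 hexamers, a planted TGATAA ranked 1 by p, and no hexamer was called with nothing planted. Those windows lay at random genome positions, so a difference in base composition between summits and flanks was not simulated.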

Results

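Binding of ELT-3 was measured by ChIP-seq in whole first-stage (L1) larvae of the nematode Caenorhabditis elegans. ELT-3 is a GATA-family transcription factor of the epidermis. The larvae came from strain OP75, an unc-119(ed3) line carrying a transgene (wgIs75) that expresses ELT-3 with a C-terminal GFP and FLAG tag. The labels give the sex as pooled male and female. The samples form 1 group of 2 biological replicates with no other genotype or stage, so the comparisons are between the replicates and between bound and unbound sequence or genes. A control was used for peak calling and was not analysed here. Read depth is unknown because only peak lists were used. Replicate 1 held 17087 peaks and replicate 2 held 7079 on the ce11 genome build, and the list from the pooled replicates held 30000. That pooled list is labelled as peaks and background, so not all of its rows need be binding sites. The set thresholded by the irreproducible discovery rate (IDR), a method meant to keep peaks ranked alike in both replicates, held 1014 peaks with a median width of 256 bp and is called the IDR set here.

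None of the 1014 rows of this IDR set was a row of the pooled ce11 list, whereas all 1043 rows of the ce10 IDR set were rows of the pooled ce10 list. Of the 1014 peaks, 989 overlapped some row of the pooled ce11 list, 958 a replicate 1 peak and 940 a replicate 2 peak, and 905 overlapped a peak in each replicate. Because the pooled list includes background, overlap with any of its rows is a weak criterion. The replicate lists are long too, with 17087 and 7079 rows. Their median q-value scores were 0.119 in replicate 1 and 0.351 in replicate 2, against 1.55 in the IDR set. Whether these scores compare between lists is not known. Overlap with any replicate row is thus also a lenient criterion, and not all replicate rows need be binding sites. Of the 1014 highest-signal pooled peaks, 623 overlapped the IDR set and 391 did not. For that reason many of the main values below stand beside those from the 1014 highest-signal pooled peaks, an alternative chosen after seeing the data. Signal values are the authors' own, one per peak, and are used to rank peaks within a list.

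The strongest peak of the IDR set lay within elt-3 itself, and 2 of the next 5 lay upstream of ribosomal protein genes. The elt-3 peak (X, 13937404 to 13937659, signal 281) lay in an intron, 2658 bp downstream of the annotated 5′ end of the gene and 1211 bp upstream of a later annotated transcript start. It ranked 7 in replicate 1 and 4 in replicate 2. The next peaks were upstream of cdc-48.1, which encodes a homologue of the ATPase p97 (II, 10563443 to 10563698, signal 243), 6372 bp upstream of Y37A1A.2 (IV, 13919273 to 13919528, signal 218), and upstream of rpl-3 (III, 3867448 to 3867703, signal 217). The rpl-3 peak ranked 1 in both replicates. Then followed iff-2, an initiation factor 5A homologue (II, 8561314 to 8561569, signal 214), and rpl-15 (IV, 654813 to 655068, signal 203).

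The other peaks among the 20 with the highest signal were nearest to dhp-1, H10E21.1, ekl-5, cbl-1, Y17G9B.5, puf-9, R11A5.6, R08D7.7, oatr-1, F26A3.4, let-607, mstr-1, rps-1 and R03E9.2. Their signals ran down to 157. The Y17G9B.5 peak (IV, 4749952 to 4750207) also lay 302 bp upstream of rpl-20. Of the 20 peaks, 11 had a WGATAR site (W is A or T, R is A or G) within 50 bp of the summit. All 20 ranked among the top 100 of replicate 2 and of the pooled list, and 19 among the top 100 of replicate 1. The exception was the peak nearest mstr-1, at rank 147.

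Around elt-3, 7 IDR peaks lay within 20 kb of the 5′ end, of which 5 had elt-3 as the nearest gene. In addition to the strongest, the introns held summits at 13936990 (signal 135), 13938120 (signal 157) and 13939537 (signal 71.9), and 1 summit lay past the 3′ end at 13941449 (signal 59.5). The remaining pair were nearest to ekl-5 (13920569, signal 198) and to alg-1, which encodes an Argonaute protein (13950949, in the 5′ UTR, signal 69.5). No IDR summit lay in the promoter window at the annotated 5′ end of elt-3, the window used for the gene lists, but 3 summits lay 189, 623 and 1211 bp upstream of later annotated transcript starts. No IDR peak lay within 20 kb of unc-119 (III, 10902641 to 10908935), the marker gene mutated in the strain. There, replicate 1 held 6 peaks and replicate 2 held 1, with signals of at most 12.01 and 20.5.

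**Figure D1:**
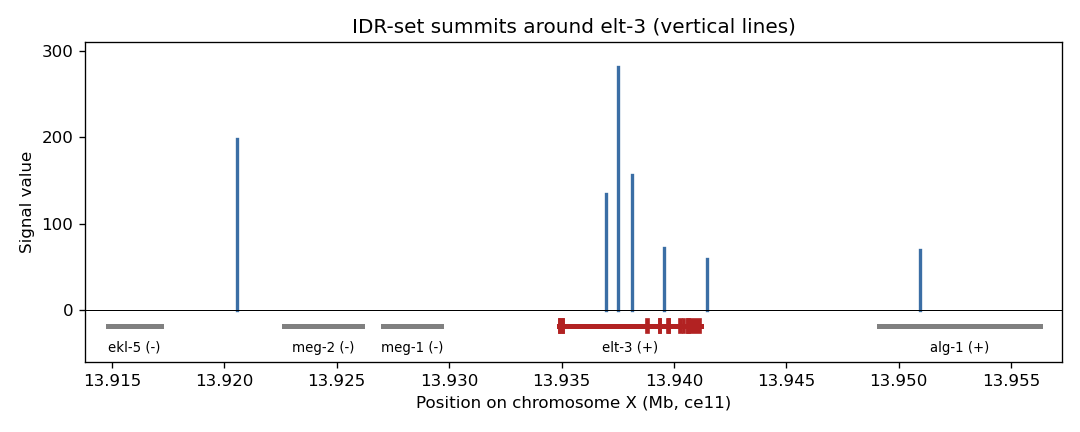
IDR-set summits around elt-3 on chromosome X. The x axis is the ce11 position in Mb and the y axis the authors' signal value (no unit); each vertical line is 1 of the 7 summits, the red bar is elt-3 with its annotated exons as boxes, and grey bars are neighbouring protein-coding genes with their strand. The highest line, at signal 281, stands in an intron of elt-3.

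Most of the strongest peaks were shared by the replicates. Of the 1014 highest-signal peaks of replicate 1, 685 (67.6%) overlapped one of the 1014 highest of replicate 2 by at least 1 bp, against a mean of 0.603% when one list was shifted around its chromosomes. None of the 1000 shifts gave more than 1.87% (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). From the side of replicate 2 the share was 67.2%. Across the 685 shared peaks the signals of the replicates correlated with Spearman's rho of 0.552, a description across peaks, which are not independent replicates. With the whole lists, whose lengths differ, 25.2% of replicate 1 peaks overlapped replicate 2 and 60.1% the other way.

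Summits were concentrated close to gene starts and in intergenic sequence, and were rare in exons. Of the 1014 summits, 467 (46.1%) lay in a promoter window, from 1500 bp upstream to 500 bp downstream of the 5′ end of a protein-coding gene, against 33.03% in shifted sets (SD 1.67 over the shifts). The 1014 highest pooled peaks gave 49.4%, and a window of 500 and 250 bp held 28.4% of the IDR summits, against 13.7%. Intergenic summits made up 62.9%, against 37.3% by chance, and exonic summits 6.51%, against 29.4%. In the pooled peaks these shares were 66.9% and 6.11%. Each of these 3 shares of the IDR set had p = 0.001, the smallest the 1000 shifts can give (two-sided permutation test). Intronic summits made up 30.6%, against 33.3% by chance (permutation test, p = 0.0849), and 27.02% in the pooled peaks, where the deficit passed (permutation test, p = 0.001). The median distance from a summit to the nearest 5′ end was 1287 bp, and 62.1% of summits lay upstream of it.

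The X chromosome held more peaks than its length would give. It held 232 summits, 22.9% of the set (95% Wilson interval 20.4 to 25.6%), and 17.7% of the nuclear genome (exact binomial test, two-sided, p = 2.58e-05). Its density was 13.1 peaks per Mb, and the autosomes ranged from 8.03 on V to 11.01 on I. In the pooled peaks the X share was 21.8% (exact binomial test, p = 8.39e-04).

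GATA sites were strongly concentrated at the summits. WGATAR occurred within 50 bp of 533 of the 1014 summits, or 52.6% (95% Wilson interval 49.5 to 55.6%), compared with 21.99% (19.6 to 24.6%) of equally wide windows 500 bp away (exact McNemar test, two-sided, p = 1.76e-43). Within 25 bp the shares were 30.97% and 11.6%. TGATAA was present at 35.1% of summits and 10.1% of flanks, and AGATAA at 14.99% and 6.51%. From the fifth of the peaks with the highest signal to the fifth with the lowest, 60.1, 52.7, 46.3, 54.7 and 49.0% of summits had WGATAR, which is not a steady fall. In the pooled peaks the share was lower, 44.9% (41.8 to 47.9%), against 21.5% in their flanks (exact McNemar test, p = 6.22e-30).

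**Figure D2:**
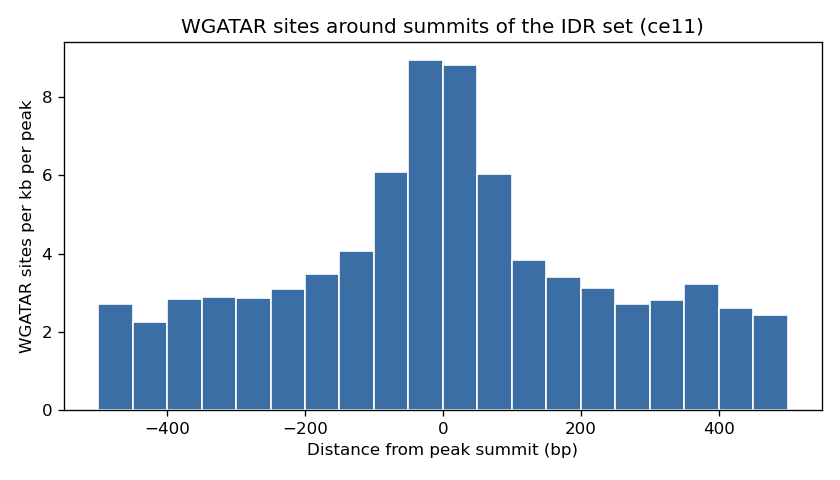
WGATAR sites around the 1014 IDR-set summits. The x axis is the distance from the summit in bp, in bins of 50 bp, and the y axis the number of sites on either strand per kb per peak; both bins next to the summit hold 8.95 and 8.84 sites per kb, compared with 2.72 and 2.43 in the outermost bins.

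Without choosing a sequence in advance, 662 of 2080 hexamers, each merged with its reverse complement, differed between summits and flanks (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment), 382 being more common at summits and 280 less, and 663 differed in the pooled peaks. Of the 10 with the lowest adjusted p, 3 were more common at summits. CTTATC, the complement of GATAAG, was at 25.5% of summits and 4.24% of flanks (Fisher's exact test, adjusted p = 8.68e-42), TGATAA at 35.1% and 10.1% (adjusted p = 3.00e-40), and GAGAGA at 26.2% and 6.02% (adjusted p = 1.49e-34). The other 7 were runs rich in A and T that were less common at summits, namely AAAATT, AAAAAT, TTAAAA, AAATTT, TAAAAA, AAAATA and ATTTTA. AAAATT, for example, was at 11.8% of summits and 42.6% of flanks (Fisher's exact test, adjusted p = 2.09e-53). Flanks were not matched to summits for base composition, so the count of 662 may in part reflect composition.

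The IDR summits fell in the promoter windows of 590 of 19973 protein-coding genes (2.95%). Genes of tyrosine and tryptophan breakdown and ribosomal protein genes were bound far more often than other genes, and chemoreceptor genes far less. These 3 of the 22 gene lists passed the test in the main analysis and in each of the 11 alternative settings tried.

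In tyrosine and tryptophan catabolism, 6 of 11 genes were bound, or 54.5% (95% Wilson interval 28.01 to 78.7%), compared with 2.93% of other genes (odds ratio 39.8, Fisher's exact test, two-sided, adjusted p = 1.93e-06). They were hgo-1, the homogentisate dioxygenase gene (WBGene00001843; I, 9055426 to 9055681, 97 bp upstream, signal 126), gst-42, a maleylacetoacetate isomerase gene (WBGene00001790; X, 11727828 to 11728083, 20 bp upstream, signal 110), tdo-2, a tryptophan dioxygenase gene (WBGene00016201; III, 5920007 to 5920262, 180 bp upstream, signal 107), kmo-1, a kynurenine monooxygenase gene (WBGene00011089; V, 12071507 to 12071762, 1116 bp upstream, signal 102), and also hpd-1 and tatn-1. The hgo-1 peak ranked 107 in replicate 1 and 96 in replicate 2. The other named peaks ranked lower, gst-42 at 170 and 481, tdo-2 at 850 and 262, and kmo-1 at 1447 and 918. With the pooled peaks 8 of the 11 genes were bound (odds ratio 76.2, Fisher's exact test, adjusted p = 1.96e-09), as they were without replicate 1 (odds ratio 75.5), and the odds ratio was 25.8 with a window of 3000 and 1000 bp.

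Of the 76 ribosomal protein genes, 22 were bound, or 28.9% (19.96 to 39.96%), against 2.85% of other genes (odds ratio 13.86, Fisher's exact test, adjusted p = 5.47e-15). The highest signals were at rpl-3 (217), rpl-15 (203), rpl-20 (186) and rps-1 (158), the last at III, 4475540 to 4475795. With the pooled peaks 29 were bound, and 14 when each IDR peak was given only to the gene with the nearest 5′ end (odds ratio 5.19). The odds ratio was 23.7 with a window of 500 and 250 bp and 23.5 in the 507 IDR peaks with the highest signal. This was the single list with at least 10 bound genes, and its bound members had strong peaks, with a median signal percentile of 78.6 among bound genes, compared with 48.7 for the other bound genes (permutation test with 100000 resamples, two-sided, p = 0.00184). In the pooled peaks the median was 75.5 (permutation test, p = 0.00235). Their summits carried GATA sites less often. WGATAR was within 50 bp of 3 of 22 summits in ribosomal protein promoters, or 13.6% (4.75 to 33.3%), and of 222 of 445 summits in other promoters, or 49.9% (45.3 to 54.5%; Fisher's exact test, two-sided, p = 7.68e-04).

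Of the 1309 chemoreceptor genes, 7 were bound, or 0.535% (0.259 to 1.1%), compared with 3.12% of other genes (odds ratio 0.167, Fisher's exact test, adjusted p = 3.39e-09). With the pooled peaks 8 were bound, and none with a window of 500 and 250 bp. Those with the highest signals were srd-65 (81.2), str-144 (77.4), str-176 (65.4) and srh-17 (52.6). Fisher's exact test treats genes as independent, and no setting matched genes for chromosome or for clustering in the genome. Peak density ran from 8.03 per Mb on V to 13.1 on X, and an effect of gene position on the low share was not tested.

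Among epidermal regulators, 3 of 16 epidermal transcription factor genes were bound (18.8%, odds ratio 7.61, Fisher's exact test, adjusted p = 0.0470), as were 3 of 17 molting genes (17.6%, odds ratio 7.07, adjusted p = 0.0470). Both lists contain blmp-1, a zinc finger repressor gene (I, 10409576 to 10409831, 402 bp downstream in an intron, signal 82.5), and nhr-23, a nuclear receptor gene needed for molting (I, 7214788 to 7215043, in the 5′ UTR, signal 46.3). The others were sma-3, which encodes a Smad (signal 51.0), and nekl-2, a NIMA-related kinase gene (signal 64.5). The nhr-23 peak overlapped no peak of replicate 1. By nearest 5′ end, with no limit on distance, 7 of the 16 transcription factor genes were bound (odds ratio 17.8). The 7 include elt-3 itself, where extra copies of the transgene were not excluded as a source of peaks. Neither list passed with the highest-signal peaks of either replicate or of the pooled list, for which the adjusted p of Fisher's exact test was 0.320 and 0.886, respectively. With only the IDR peaks overlapped in both replicates, an alternative added for the lists after seeing the data, 2 genes of each list were bound and neither passed (Fisher's exact test, adjusted p = 0.279).

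Of the 12 excretory cell genes, 3 were bound (25%, odds ratio 10.997, Fisher's exact test, adjusted p = 0.0254). All were subunits of the vacuolar proton ATPase, vha-1, vha-5 and vha-8, with signals of 49.0, 46.3 and 48.9, near the lower end of the set. These are the only vacuolar ATPase genes in the list, and none of its other members was bound. The call thus rests on this 1 family and says nothing of the other excretory cell genes. In replicate 1, replicate 2 and the pooled list, the vha-1 peak ranked higher, at 146, 229 and 163, and the vha-8 peak at 306, 705 and 449. The vha-5 peak ranked 3911, 3188 and 2870. The call for this list too was lost with the pooled peaks (Fisher's exact test, adjusted p = 0.225) and with those of either replicate. In each of these settings 2 of the 12 genes were still bound, with an odds ratio of 5.67 for the pooled peaks.

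Of the genes for epidermal antimicrobial peptides, 3 of 22 were bound (13.6%, Fisher's exact test, adjusted p = 0.0818), which did not pass. One peak (V, 3979914 to 3980169, signal 133) lay 13 bp upstream of nlp-31 and 908 bp upstream of nlp-34, and another upstream of nlp-24, which overlapped no peak of replicate 1, had a signal of 55.0. With the pooled peaks 4 were bound and the list passed (Fisher's exact test, adjusted p = 0.0332). For cuticle collagen genes no difference passed the test, with 9 of 174 bound (5.17%, 2.74 to 9.54%, Fisher's exact test, adjusted p = 0.295), and 7 bound in the pooled peaks (Fisher's exact test, adjusted p = 0.923). Those with the highest signals were col-62 (95.4), col-10 (83.3), and col-117 and col-3, which shared a peak (62.3).

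The other epidermal lists did not pass and held 1 bound gene each of 13 for collagen processing (mlt-7, a peroxidase gene, signal 48.6), of 40 for apical matrix ZP proteins (cut-2, 48.9, at a peak that overlapped none of either replicate), of 19 for attachment and junctions (mup-4, 48.9) and of 11 for the osmotic response (osm-11, 51.7). The hedgehog-related and patched-related list held 3 of 83 (grl-11, grl-17 and ptr-25). Of the histone genes, 1 of 72 was bound (his-37, signal 116). No promoter was bound in the lists for seam cell genes (12 members), GATA factors (11, including elt-3, whose summits lay outside the window at its 5′ end), oxidative and heat stress (23), intestine (24), body wall muscle (21), pharynx (15), neurons (30) and germline (22). Lists of this size would often hold no bound gene at the genome-wide share of 2.95%, and their upper 95% Wilson limits ran from 11.4 to 25.9%.

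**Figure D3:**
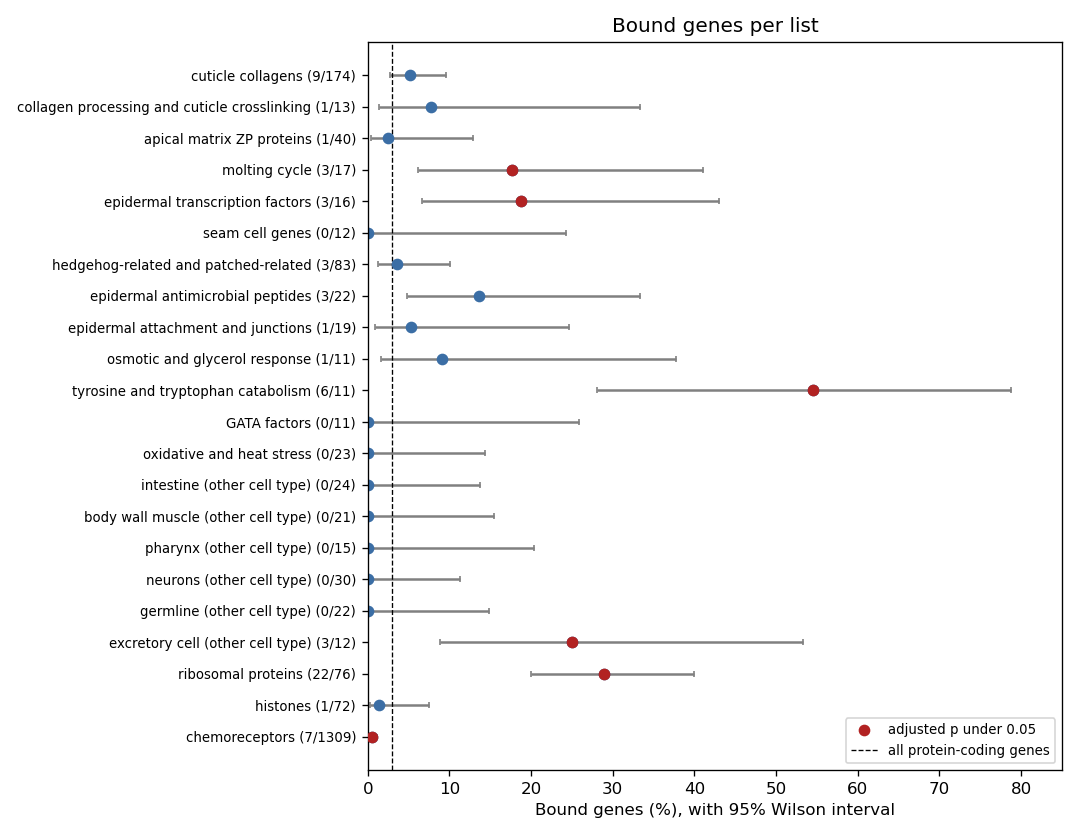
Share of genes bound in each of the 22 lists. The x axis is the percentage of genes with an IDR summit in the promoter window, each point is 1 list with its 95% Wilson interval, red points had an adjusted p under 0.05, the dashed line is the share of all protein-coding genes (2.95%), and the counts beside each name are bound genes over members. Tyrosine and tryptophan catabolism (54.5%) and ribosomal proteins (28.9%) lay farthest to the right.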

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

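The tests of identical rows, of correlations with equal truncation and of top-list overlaps were chosen after the mismatch between the ce11 lists had been seen, as were the ribosomal tests on pooled peaks and flanks and the peak counts by distance from elt-3.

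Of the 1014 highest-signal peaks of the pooled ce11 list, 391 overlapped no peak of the IDR set, a signal outside the peaks used for the main values. WGATAR lay within 50 bp of 36.1% of these 391 summits (95% Wilson interval 31.5 to 40.9%), and of 51.8% (46.8 to 56.7%) of the 392 IDR peaks that overlapped none of the pooled top peaks (Fisher's exact test, two-sided, p = 1.09e-05). No biological explanation was tested.

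For the mismatch between those ce11 lists, a different threshold on the deposited pooled list is argued against, since 0% of the IDR rows were rows of that list. A second peak call on the same reads stays open. Over 905 matched peaks, rho between IDR and pooled signal minus rho between the replicates was -0.166 (95% bootstrap interval -0.221 to -0.114), the outcome set in advance against it. That comparison was uneven, because the IDR set is truncated by its own signal while the replicate lists were not, and with equal truncation the difference was -0.0371 (-0.0985 to 0.0192), so a second call on the same reads cannot be told apart from a call on other reads. The IDR set shared 61.3% (58.3 to 64.3%) of its peaks with the pooled top peaks, and the replicates 67.6% (64.6 to 70.4%) with each other. With the top peaks of replicate 1 and replicate 2 the IDR set shared 57.7% and 59.3%, and the pooled top peaks shared 78.5% and 87.4%. The IDR set was thus less like each replicate than the replicates were like each other. Other reads, another control or other settings may be involved.

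Peaks were dense around elt-3, with 22 replicate 1 and 19 replicate 2 peaks within 20 kb of its 5′ end, compared with medians of 6 and 2 around protein-coding genes. Extra copies of the transgene may raise the signal over the loci it carries. The peak count at elt-3 was at percentile 99.9 in the lower replicate, which this explanation needs, but that at unc-119 was at percentile 35.9, so the test, set in advance to need both, left it open, and the labels do not say which interval or which unc-119 copy the transgene holds. In replicate 1 the 20 kb on either side of the elt-3 5′ end held 11 peaks each, and the adjoining 20 kb held 2 and 3. Binding of ELT-3 to its own gene remains open as the biological explanation and was not tested.

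Ribosomal protein promoters were among the strongest bound. A hypothesis is that they were occupied, or enriched, without contact of ELT-3 with a GATA site. The test set in advance, which could have shown as many sites as elsewhere, found WGATAR at 13.6% of ribosomal promoter summits and 49.9% of other promoter summits (Fisher's exact test, two-sided, p = 7.68e-04), and in the pooled peaks at 7.14% and 40.2% (Fisher's exact test, p = 2.14e-04). WGATAR was in 2 of the 22 ribosomal flanks (9.09%) and in 18.9% of flanks of other promoters, a difference that was not tested. Against their own flanks, summits in other promoters had more sites (exact McNemar test, p = 9.73e-21). For the 22 ribosomal summits no difference from their flanks passed, a comparison with few summits. The summit shares do not show how these promoters came to be enriched. Enrichment of highly transcribed promoters in any ChIP, and recruitment by other proteins, may each give this pattern, and neither was tested because no other factor or control was analysed here.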

How the results depend on the processing

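The 1014 highest-signal pooled peaks, the peaks of single replicates for hexamers, and the IDR peaks overlapped in both replicates for results other than the peak count were alternatives chosen after seeing the data. No paired analysis was possible because there is only 1 group of samples. Depth limits could not be assessed, since the lists give no read counts. Single-replicate and pooled top peaks were as many as the IDR set by construction, so they give no value for the peak count, and the logistic model gave none for lists without a bound gene. Replicate agreement, the promoter, exon, intergenic, X and GATA shares and the strength of ribosomal peaks kept their direction and their side of the threshold in each alternative run, and the hexamer count stayed between 486 and 689. The promoter share ranged from 28.4 to 62.3% with the window, and whole lists gave an agreement of 25.2%. The intron deficit passed in the 507 peaks (28.8%), with pooled peaks (27.02%) and without 1 replicate (27.2 to 27.6%), and the cause was not tested. Ranks of the 20 named peaks among the IDR peaks moved by more than 1 SD of the ranks in the 2 replicates in 46 of 60 recomputed values. That SD rests on 2 of the recomputed ranks themselves, so it is small where the replicates agree. The rpl-15 peak, at rank 6, counted as moved at 7 and 8. The mstr-1 peak, at 18, did not at 34 without replicate 1 or 44 in the pooled list. The count of 46 therefore does not measure how far the ranks shifted.

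The set held 507 peaks when restricted to the highest-signal ones, by construction. In that subset 3 lists passed in place of 6, and 3 also passed with the window of 500 and 250 bp. Odds ratios of the calls that were lost follow, and the cause was not tested. For molting genes they were 7.83 with the 500 and 250 bp window, 5.89 against lettered genes, 8.28 in the 507 peaks, 4.80 in peaks overlapped in both replicates, 1.77 with pooled peaks, and 1.79 to 3.74 without 1 replicate. For epidermal transcription factors they were, in that order, 8.39, 6.34, 4.13, 5.15, 4.05, and 4.01 to 4.09. For excretory cell genes they were 4.54 by nearest gene, 11.7 with the 500 and 250 bp window, 0 in the 507 peaks, 5.67 with pooled peaks, and 5.62 to 5.73 without 1 replicate. Antimicrobial peptides gained the call at 4.77 with the 3000 and 1000 bp window, 6.32 with pooled peaks, 5.16 in the logistic model, and 6.26 to 6.38 without 1 replicate. The main odds ratio was 5.21, with the same 3 of 22 genes bound as in the logistic model. That model replaced Fisher's exact test and was adjusted over 14 lists in place of 22, so its gain does not show a stronger association.

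Among the 15 lists that passed in no setting, those named next changed direction and the others did not. By nearest gene the odds ratios were 0.276 for hedgehog-related, 2.27 for GATA factor (from elt-3 itself), 2.16 for stress, 2.52 for neuronal and 1.08 for germline genes. With the 3000 and 1000 bp window they were 0.802 for hedgehog-related, 2.38 for neuronal and 2.14 for germline genes, and with the 500 and 250 bp window 0 for hedgehog-related genes. In the 507 peaks they were 0 for collagen processing, attachment and osmotic genes. With pooled peaks they were 2.57 for seam, 1.29 for stress and 1.23 for histone genes. Without 1 replicate they ran from 0 to 2.60 for seam, 0 to 1.56 for attachment, 1.27 to 1.3 for stress, 0 to 1.24 for intestine and 1.22 to 1.24 for histone genes.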

Other observations

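The values in this part were looked for after the main results had been seen, and no explanation was tested for them.

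Some sequences other than GATA were more common at summits than in flanks. The flanks were not matched for base composition, so these differences may in part reflect composition. GAGAGA, at 26.2% of IDR summits, was about as frequent in summits with a WGATAR site (24.4%) as in those without one (28.3%; Fisher's exact test, two-sided, p = 0.174). At least 1 of GAGAGA and WGATAR was present at 66.0% of summits. It was least frequent in the fifth of peaks with the highest signal, at 15.8%, compared with 23.6 to 34.5% in the other 4 groups by signal. GACGCA was at 10.7% of summits and 1.28% of flanks (Fisher's exact test, adjusted p = 6.66e-19). It was less frequent in summits with WGATAR (7.69%) than in those without it (13.9%; Fisher's exact test, two-sided, p = 0.00151), and the pooled peaks gave 8.35% and 15.7% (Fisher's exact test, p = 3.78e-04). Of the 22 summits in ribosomal protein promoters, 6 held GACGCA and 2 held GAGAGA.

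Of 175 gene classes with at least 10 members, defined by the letters of the gene symbol, 2 were bound more often than other genes after adjustment, rpl (16 of 47) and rps (8 of 31), which count ribosomal protein genes together with symbols outside the fixed list. The next by p were vha, the vacuolar ATPase subunits (4 of 20, Fisher's exact test, p = 0.00250, adjusted p = 0.146), and ugt, the glucuronosyltransferases (7 of 67, Fisher's exact test, p = 0.00356, adjusted p = 0.156), which did not pass. Apart from elt-3, 2 genes were nearest to 5 IDR peaks each, mdl-1, a Mad-family transcription factor gene, and nhr-3, a nuclear receptor gene.

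In the pooled peaks 13 of 1014 summits (1.28%) lay within 200 bp of a tRNA gene, compared with 0.300% in shifted sets (permutation test, two-sided, p = 0.001, the smallest the shifts can give). In the IDR set 6 did (0.592%, against 0.305%, permutation test, p = 0.129).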
